A study of Caenorhabditis elegans with 6 samples.

How the data were processed

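Poly(A)-selected RNA of whole fourth-stage (L4) larvae of *Caenorhabditis elegans* was sequenced from the laboratory wild-type strain N2 and from the strain carrying the on33 allele of mstr-1, with 3 libraries per genotype that the labels call biological replicates. Animals were grown at 20 degrees C on plates with OP50 bacteria, and the libraries were directional and read from both ends, per the labels' protocols. Per the submitters' processing notes the authors used, in an order and with roles not given there, FastQC 0.11.2, Trim Galore 0.4.0 with cutadapt, TopHat2 2.0.11, HTSeq 0.6.1p2, DESeq 1.18.0, edgeR 3.16.5 and R 3.3.2, with the genome build WBcel235. Whether reads were counted by strand, and how reads of several genes were treated, is not given in the sources used here.

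The values used are RPKM, reads divided by gene length in kilobases and scaled to the library total, as deposited by the authors for each library. The same tables hold, per the file headers, a log2 fold change, a mean log2 CPM, an F score, a p-value and an adjusted p-value (FDR) from the authors' model of batch and group. One table lists 45043 genes and a filtered table lists 13839 of them with the same RPKM to within 4.6e-06. For 876 genes the full table holds no RPKM, and these were left out. Genes were matched by their numeric gene identifier: 44893 of 45043 identifiers had a name in the RefSeq table of WBcel235, of which 1411 were newer than the listed name, and 11 symbols of the filtered table had the form of dates. The mstr-1 gene appears under its older name F22D6.2. Coordinates are those of the Ensembl annotation of WBcel235.

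The RPKM values of a gene were whole multiples of the value of 1 read, so reads could be recovered for 21309 of the 21311 genes above 0 in at least 2 libraries, with a relative tolerance of 1e-09. The gene lengths behind the RPKM are called coding lengths. Of the protein-coding genes checked, 98.5% had a length that was a multiple of 3 and 84.5% had exactly the annotated coding length. The reads of a gene were multiplied by a common factor where this brought its length close to the annotated one. These shares are therefore not independent of the annotation. Of 1439 noncoding genes, 1196 gave the same library totals. These totals were 38663387, 42870578 and 42338526 reads for N2 replicates 1 to 3 and 44225329, 42756170 and 41551696 for mstr-1(on33) replicates 1 to 3. Intervals on ratios of reads are exact (Clopper-Pearson) 95% intervals over the pooled reads of a genotype and cover counting error only.

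The test, its samples, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. That plan held a count model for count tables and a test on log values for normalized units. As the deposited unit is RPKM, the latter was used: limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a variance trend, on log2(RPKM + 0.5), for the 16033 genes with a mean RPKM of at least 0.5 over the 6 libraries. The model held the replicate number as a block and the genotype, because the deposited comparison is named for batch and group. The authors' log2 fold changes of 800 genes differed from those of a gamma model with the replicate number as batch by an SD of 0.00327, against 0.0996 with no batch. The next closest coding, with replicates 1 and 2 exchanged in 1 genotype, gave an SD of 0.0106. Adjusted p-values are Benjamini-Hochberg values at 0.05. Fold changes are on the log2(RPKM + 0.5) scale, which understates changes of genes with low values. In simulated data with the spread of the 16033 genes, 0 of 50 genes changed by 1 log2 unit were called, 8 of 50 changed by 2, 26 of 50 changed by 4 and 43 of 50 changed by 10, with 2 false calls.

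Of 46 gene lists, 43 had at least 3 tested members. Lists were tested with camera of limma at a preset correlation of 0.01, on log2(RPKM + 0.5) in place of the planned log-CPM, with Benjamini-Hochberg adjustment over the 43 lists. Alternatives were camera with an estimated correlation and the rotation test fry. Both rest on the 2 residual degrees of freedom of the main fit, so after adjustment over 43 lists they could hardly call any list. In simulated data with 33 proteasome genes raised by 0.5 log2 units, that list was called and 0 of the other lists were. The genes were simulated independently of each other, so this does not show how often lists of correlated genes are called falsely. Exact permutation tests of list means were two-sided over all assignments of 3 libraries against 3, for which the smallest possible p is 0.1.

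The rule for named genes takes mstr-1, then up to 12 genes per direction with the largest log2 fold change among those past 0.05 whose values moved alike in all 3 same-numbered pairs at a mean CPM of at least 1, and in each called list the 4 members with the smallest p that moved in the direction of the list. Of the genes that this rule names, 1 is not reported here and the others are. Other genes are said to be chosen after their values were seen. Other settings fixed with the plan and run were no replicate block, pseudocounts of 0.1 and 1, no filter on low values, the genes of the authors' filtered table, an added minimum log2 fold change of 1, a test against a log2 fold change of 0.58 with limma's treat, and leaving out each library. Chosen after seeing the data were a mean RPKM of at least 5, median-of-ratios and upper-quartile scaling, limma's voom on recovered reads for genes with a mean of at least 10 reads, a robust variance prior, and the moulting score as covariate in place of the block. The moulting score is the mean of the moulting gene list in each library. Figures were drawn with matplotlib 3.10.9, and intervals were computed with scipy 1.17.1 in Python 3.11.15.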

Results

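The series asked how loss of mstr-1 affects messenger RNA levels across the genome of the nematode *C. elegans*. RNA of whole L4 larvae was compared between N2, the wild-type reference strain, and a strain with the on33 allele of mstr-1, with 3 libraries each. Library totals ran from 38663387 reads (N2 replicate 1) to 44225329 (mstr-1(on33) replicate 1), and 16033 genes passed the minimum of expression. Values are RPKM given as mean ± SD over 3 libraries, and fold changes are mstr-1(on33) over N2 on the log2(RPKM + 0.5) scale with their standard error.

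RNA of the targeted gene was nearly absent from the mutant libraries. mstr-1 (F22D6.2, WBGene00009050) lies on the minus strand of chromosome I from 7079562 to 7082040 in WBcel235 and has a coding length of 570 bp. It was expressed at 549 ± 56.0 RPKM in N2 (SD, n = 3), from 13291, 12003 and 13309 reads in replicates 1 to 3. The mutant libraries held 2, 0 and 0 reads of it. Over the pooled reads the mutant level was 0.00499% of the N2 level, with an exact 95% interval of 0.000605% to 0.0180%. In the limma fit the log2 fold change was −10.03 ± 0.24 (adjusted p = 0.00259), a size that depends on the pseudocount. The sequence change of on33 is not given in the sources used here. The adjusted p was 0.545 without N2 replicate 1, 0.0791 without N2 replicate 2 and 0.327 without mstr-1(on33) replicate 1, at log2 fold changes from −10.07 to −9.98. In the authors' deposited table the log2 fold change of mstr-1 was −14.08 with an adjusted p of 0.187.

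kin-14, a protein kinase gene, lies directly downstream of mstr-1 on the same strand, from 7075918 to 7079575, so that the annotated genes share 14 bp (7079562 to 7079575). It had 23.7 ± 5.01 RPKM in N2 and 60.1 ± 3.80 in the mutant (SD, n = 3), with every mutant library above every N2 library. The log2 fold change was 1.34 ± 0.23, with an unadjusted p of 0.00232 and an adjusted p of 1.00 by limma, so it did not pass the threshold. Of the other genes of the neighbourhood, the 6 nearest tested ones had log2 fold changes from −0.06 to 0.32, among them W01A8.6 downstream at −0.06 ± 0.26 and nars-1 upstream at 0.17 ± 0.18. These genes were chosen after their values were seen, and how reads in the shared 14 bp were assigned is not given in the sources used here.

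**Figure D1:**
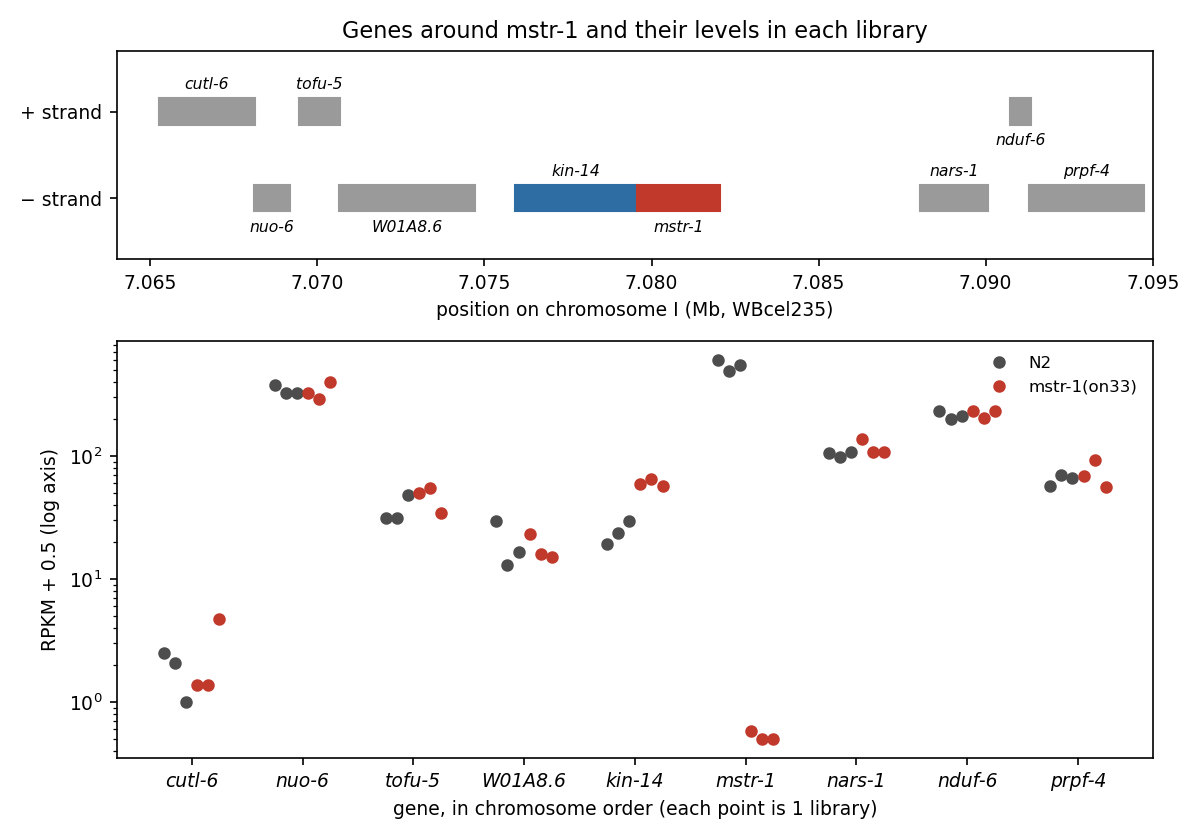
Upper panel: the annotated genes tested around mstr-1 on chromosome I (Mb, WBcel235), drawn to scale by strand. Lower panel: RPKM + 0.5 of each gene on a log axis, one point per library, grey for N2 and red for mstr-1(on33); mstr-1 has a mean of 549 RPKM in N2 and 0.0264 in the mutant, and kin-14 has 23.7 and 60.1.

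Across the 16033 genes, mstr-1 was the only one past an adjusted p of 0.05, with 0 genes higher and 1 lower by limma. An unadjusted p under 0.05 was reached by 575 genes, fewer than the about 802 that chance gives. The number ran from 123 without N2 replicate 2 to 3115 without mstr-1(on33) replicate 3. It was 1249 without the replicate block, above the number that chance gives, and 2231 with the moulting score in place of the replicate number. Among the genes of the authors' deposited tables, 0 had an adjusted p under 0.05, while 670 of the full and 572 of the filtered table had an unadjusted p under 0.05. The count of genes past an adjusted p of 0.05 was 0 without N2 replicate 1, without N2 replicate 2 and without mstr-1(on33) replicate 1. In the fit without the replicate block it was 2, with BE0003N10.6 besides mstr-1.

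After mstr-1, the smallest p-values among protein-coding genes belonged to genes whose adjusted p did not pass, named here after their values were seen. kin-14, given above, and irg-5, given below with its list, are also among them. BE0003N10.6 (chromosome III, 1056230 to 1060061) had 88.995 ± 6.94 RPKM in N2 and 3.66 ± 2.05 in the mutant, from 3432, 4450 and 4089 reads against 87, 153 and 264 (log2 fold change −4.54 ± 0.34, adjusted p = 0.358 by limma, and 0.0450 to 1.00 over 18 other settings of the fit). The neighbouring gtnt-18 and gtnt-17 on chromosome V (8118264 to 8120417 and 8121168 to 8123470) were at 11.9 ± 3.40 and 18.4 ± 3.42 RPKM in N2 and at 0.705 ± 0.4995 and 0.595 ± 0.743 in the mutant. Their log2 fold changes were −3.41 ± 0.46 and −4.30 ± 0.53, while the next gene of the family, gtnt-16, had −0.13 ± 0.65. F07E5.9 was at 0.115 ± 0.0534 RPKM in N2 and 1.63 ± 0.569 in the mutant, from 18 and 259 pooled reads. The adenine nucleotide translocator gene ant-1.3 had −1.02 ± 0.19 and the cystatin gene cpi-1 had −0.96 ± 0.18. For T27A3.5, Y1A5A.1 and melo-3 the log2 fold changes were −1.02 ± 0.21, −0.98 ± 0.20 and −1.13 ± 0.23.

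Genes of the proteasome, the complex that degrades ubiquitin-tagged proteins, were higher in mstr-1(on33). Of the 33 subunit genes measured, 32 were higher, with log2 fold changes from 0.32 for rpn-12 to 0.66 for pas-1 and a list median of 0.51. The exception was rpn-6.2, at −0.45 ± 0.22, while its paralog rpn-6.1 was at 0.60 ± 0.16, both named after their values were seen. In 33 of 33 genes the 3 mutant libraries and the 3 N2 libraries did not overlap, where chance gives 10% for a single gene. Genes that move together in the same 6 libraries are not independent trials, so this share is no test. pbs-4 stood at 277 ± 10.2 RPKM in N2 and 429 ± 31.1 in the mutant, pas-1 at 226 ± 11.4 and 357 ± 34.8, pas-5 at 233 ± 3.77 and 344 ± 19.03, and rpn-11 at 182 ± 7.78 and 276 ± 25.6 (SD, n = 3). The list was called by camera with the preset correlation (adjusted p = 2.96e-30), and 27 of the 33 genes had an adjusted p under 0.05 adjusted over the list alone, against 0 over all genes tested and 28 at an unadjusted p under 0.05. With an estimated correlation between genes of 0.62 the adjusted p was 0.885 (unadjusted p = 0.0972), and fry gave an adjusted p of 0.7503. The list means of the mutant libraries were 0.32, 0.29 and 0.12 for replicates 1 to 3 and those of N2 were −0.23, −0.26 and −0.23 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows).

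**Figure D2:**
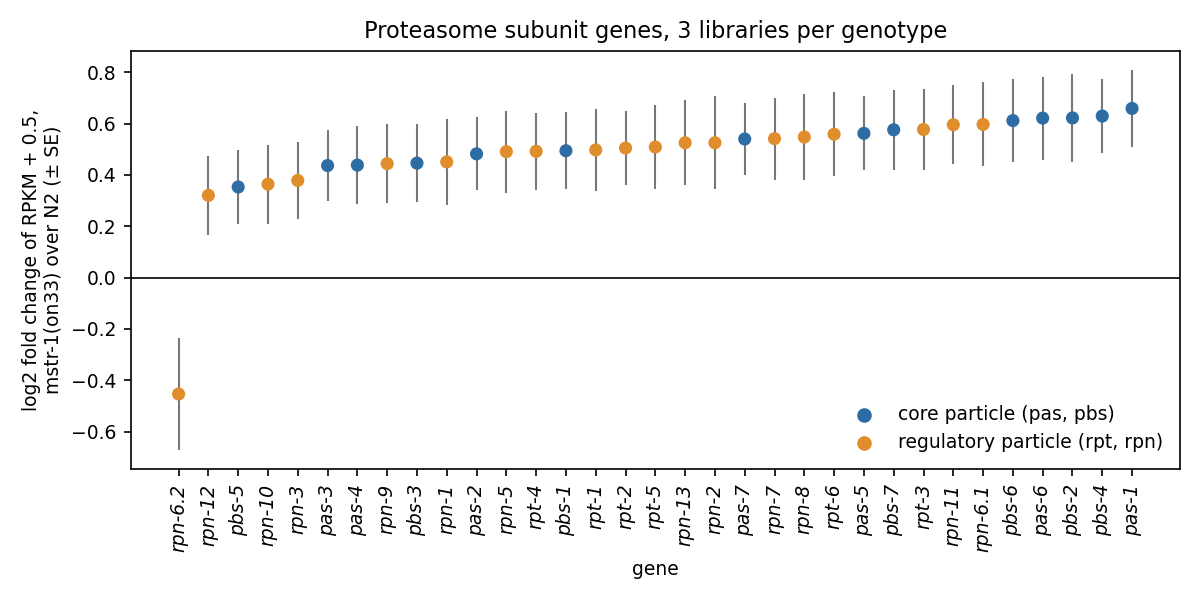
Log2 fold change of RPKM + 0.5, mstr-1(on33) over N2, for each of 33 proteasome subunit genes, with bars of 1 SE from the limma fit and 3 libraries per genotype. Core particle genes (blue) and regulatory particle genes (orange) lie between 0.32 and 0.66, except rpn-6.2 at −0.45.

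Sperm genes were lower in the mutant. All 29 major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, had negative log2 fold changes with a median of −1.12 (camera, adjusted p = 4.18e-19), and 22 of 23 other spermatogenesis genes did, with a median of −0.81 (adjusted p = 8.30e-12). With an estimated correlation the adjusted p of both was 0.885, and 0 genes of either list passed 0.05 adjusted over the list alone. An unadjusted p under 0.05 was reached by 8 and 4 of their genes. msp-40 had 530 ± 207 RPKM in N2 and 217 ± 40.6 in the mutant, and msp-63 had 16.01 ± 11.3 and 2.25 ± 0.647, with msp-50 and msp-81 at log2 fold changes of −1.27 ± 0.42 and −1.0995 ± 0.39. The kinase gene spe-6 had 30.99 ± 6.91 and 16.23 ± 1.46 RPKM, and the phosphatase genes gsp-3 and gsp-4 had log2 fold changes of −0.996 ± 0.34 and −0.99 ± 0.37. The spread within N2 was wide, with list means of the major sperm proteins of −0.23, 0.63 and 1.27 in N2 replicates 1 to 3 and −0.11, −0.60 and −0.97 in mstr-1(on33) replicates 1 to 3 (exact permutation p = 0.2, two-sided). Those of the other spermatogenesis genes were −0.08, 0.47 and 0.72 in N2 and −0.18, −0.26 and −0.67 in the mutant (exact permutation p = 0.1, two-sided, the smallest possible). The libraries of the genotypes did not overlap in 7 of 29 major sperm protein genes and 11 of 23 other spermatogenesis genes. Chance gives 10% for a single gene, but the genes of these lists move together, with estimated correlations of 0.92 and 0.49. Without replicate 1 of either genotype the median of the major sperm proteins was −1.78, and without replicate 3 it was −0.56 and that of the other spermatogenesis genes −0.42. Major sperm protein genes are near-identical copies, and how reads matching several of them were counted is not given in the sources used here.

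Lists of oocyte, yolk and germ line genes were higher in the mutant by the preset correlation, but their libraries did not separate by genotype. The oocyte and eggshell list had a median of 0.75 (adjusted p = 0.00112 by camera) with 17 of 17 members positive, among them spn-4 at 0.91 ± 0.66, mex-3 at 0.75 ± 0.64, mei-2 at 0.72 ± 0.61 and lin-41 at 0.68 ± 0.53. The vitellogenins, the yolk proteins, had a median of 0.93 (adjusted p = 0.0407), from vit-1 at 0.84 ± 0.29, vit-6 at 1.64 ± 1.12, vit-2 at 1.88 ± 1.33 and vit-5 at 1.01 ± 2.15. Germ line and meiosis genes had a median of 0.34 (adjusted p = 8.67e-06), led by nos-3 at 0.49 ± 0.24, glh-1 at 0.34 ± 0.17, pgl-1 at 0.41 ± 0.24 and htp-2 at 0.51 ± 0.31. Cell cycle and DNA replication genes had 0.36 (adjusted p = 3.27e-04; rnr-1 at 0.37 ± 0.18, rnr-2 at 0.58 ± 0.34, cdk-2 at 0.45 ± 0.30, mcm-6 at 0.46 ± 0.31), small RNA pathway genes 0.29 (adjusted p = 9.66e-04; csr-1 at 0.53 ± 0.23, wago-4 at 0.48 ± 0.31, ego-1 at 0.38 ± 0.28, prg-1 at 0.30 ± 0.23) and DNA damage genes 0.26 (adjusted p = 0.00602; rad-51 at 0.38 ± 0.27, brc-1 at 0.37 ± 0.34, atl-1 at 0.30 ± 0.28, mrt-2 at 0.26 ± 0.24). With an estimated correlation the adjusted p of each of these lists was 0.885, and 0 of their genes passed 0.05 adjusted over the list alone, with vit-1 the 1 gene at an unadjusted p under 0.05. Without replicate 1 of either genotype, whose removal gives the same estimate in a blocked model, all 6 calls were lost, with medians of 0.11 for oocyte, −0.04 for vitellogenin, 0.21 for germ line, 0.16 for cell cycle, 0.15 for small RNA and 0.16 for DNA damage genes. The vitellogenin call was lost in 8 of 17 other settings of the fit. Without replicate 2 of either genotype the calls of oocyte (0.25), vitellogenin (0.47) and DNA damage genes (0.09) were lost. The medians of germ line and cell cycle genes were 0.12 and 0.19 there. Without replicate 3 medians rose to 1.92 for oocyte, 2.81 for vitellogenin, 0.67 for germ line, 0.75 for cell cycle and 0.52 for DNA damage genes. The small RNA median ran from 0.14 to 0.51 over the fits that left out 1 library.

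These lists moved with a difference among libraries that did not follow genotype. The first principal component, with 43.9% of the variance, set N2 replicates 1 and 2 and mstr-1(on33) replicate 3 on one side and N2 replicate 3 and mstr-1(on33) replicates 1 and 2 on the other. The oocyte list mean was −1.12, −0.68 and 0.70 in N2 replicates 1 to 3 and 0.98, 0.98 and −0.87 in mstr-1(on33) replicates 1 to 3. The moulting gene list ran the other way, at 0.66, 0.31 and −0.59 in N2 and −0.47, −0.88 and 0.98 in the mutant, and was not called between genotypes (median −0.19, adjusted p = 0.1497). The proteasome list followed this division in the mutant only, where replicate 3 stood above every N2 library but below the other mutant libraries. In N2 it did not, with list means of −0.23 and −0.26 in replicates 1 and 2 and −0.23 in replicate 3.

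**Figure D3:**
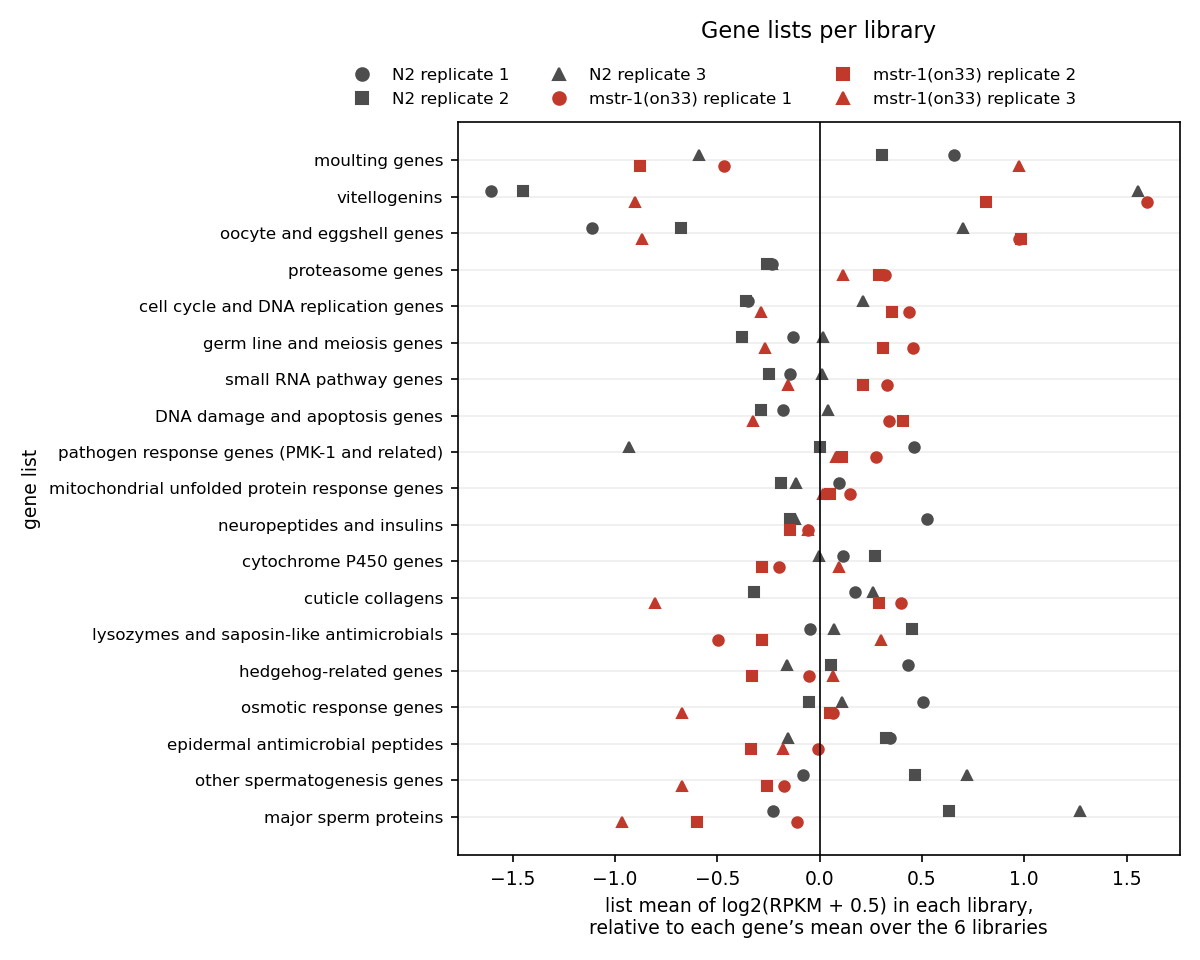
Mean of each called gene list, and of the moulting genes, in each library, as log2(RPKM + 0.5) relative to each gene's mean over the 6 libraries; grey symbols are N2 and red symbols mstr-1(on33), with the shape giving the replicate number. Proteasome means of N2 lie between −0.26 and −0.23 and those of the mutant between 0.12 and 0.32, while oocyte means overlap between the genotypes.

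The lists of epidermal antimicrobial peptides, lysozymes, cytochrome P450 genes, cuticle collagens and neuropeptides were lower in the mutant by the preset correlation. Epidermal antimicrobial peptides had a median of −0.44 (adjusted p = 0.00443 by camera), with nlp-30 at 127 ± 23.1 RPKM in N2 and 62.1 ± 22.9 in the mutant, and with nlp-33, cnc-4 and nlp-29 at log2 fold changes of −0.50 ± 0.14, −0.996 ± 0.30 and −0.60 ± 0.19. Lysozymes and saposin-like genes had −0.21 (adjusted p = 0.00496; lys-10 −2.31 ± 0.59, lys-3 −1.78 ± 0.72, ilys-2 −1.46 ± 0.62, ilys-3 −1.103 ± 0.34). Cytochrome P450 genes had −0.19 (adjusted p = 0.00811), with cyp-35A2 at 88.0 ± 31.97 RPKM in N2 and 38.5 ± 2.38 in the mutant, cyp-35A3 at −1.79 ± 0.40, cyp-35A4 at −1.23 ± 0.44 and dach-1, listed as cyp-34A4, at −1.01 ± 0.27. Cuticle collagens had a median of −0.20 and a mean of −0.08 (adjusted p = 0.00443), with col-97 at 1566 ± 87.9 RPKM in N2 and 1152 ± 63.2 in the mutant, col-63 at −0.66 ± 0.20, col-14 at −0.47 ± 0.16 and dpy-5 at −0.49 ± 0.17. Neuropeptides and insulins had −0.17 (adjusted p = 9.66e-04), with the same nlp-29, nlp-30 and nlp-33 and flp-33 at −0.84 ± 0.30 as the members with the smallest p. With an estimated correlation the adjusted p of each of these lists was 0.885, and 0 of their genes passed 0.05 adjusted over the list alone. An unadjusted p under 0.05 was reached by 6 of 19 epidermal peptide, 2 of 35 lysozyme, 4 of 53 cytochrome P450, 8 of 137 collagen and 6 of 135 neuropeptide genes. Over all 16033 genes tested it was reached by 575. The list means of the libraries overlapped between genotypes in each list. Cuticle collagen means were 0.17, −0.32 and 0.26 in N2 replicates 1 to 3 and 0.40, 0.29 and −0.81 in mstr-1(on33) replicates 1 to 3. Neuropeptide means were 0.52, −0.15 and −0.12 in N2 and −0.06, −0.14 and −0.06 in the mutant (exact permutation p = 0.9, two-sided). The same test gave 0.2 for the epidermal peptides, 0.3 for the lysozymes and 0.2 for the cytochrome P450 genes. Leaving out replicate 2 of either genotype ended the calls of the epidermal peptides (−0.12), lysozymes (0.011) and cytochrome P450 genes (−0.12), replicate 1 those of the lysozymes (−0.14) and neuropeptides (0.043), and replicate 3 turned the cuticle collagens to 0.23.

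Hedgehog-related genes had a median of −0.23 (adjusted p = 0.0497; wrt-4 −0.77 ± 0.29, grd-11 −0.72 ± 0.43, hog-1 −0.42 ± 0.30, grl-5 −0.74 ± 0.62) and osmotic response genes −0.26 (adjusted p = 0.0450; nlp-29 as above, gpdh-1 −0.74 ± 0.53, gpdh-2 −0.25 ± 0.23, hmit-1.1 −0.90 ± 0.91). Higher, at adjusted p close to the threshold, were the mitochondrial unfolded protein response genes, with a median of 0.15 (adjusted p = 0.0444; ubl-5 0.45 ± 0.16, hsp-6 0.27 ± 0.15, dve-1 0.50 ± 0.32, timm-17B.1 0.23 ± 0.15), and pathogen response genes of the PMK-1 and related pathways, with a median of 0.22 (adjusted p = 0.0496). In the latter list irg-5, an infection response gene, was at 4.93 ± 2.07 RPKM in N2 and 23.5 ± 3.84 in the mutant (log2 fold change 2.22 ± 0.32) and was the 1 member past 0.05 adjusted over the list alone. sysm-1 was at 1.32 ± 0.44, clec-85 at 0.42 ± 0.23 and clec-60 at 0.92 ± 0.53. Of 17 other settings of the fit, 12 ended the hedgehog-related and mitochondrial calls and 8 ended or turned the osmotic and pathogen response calls. With an estimated correlation the adjusted p of all 4 lists was 0.885, and their library means overlapped between genotypes. In the other lists of the 4, 0 genes passed 0.05 adjusted over the list alone and wrt-4, nlp-29 and ubl-5 had an unadjusted p under 0.05. Leaving out replicate 1 of either genotype ended the calls of hedgehog-related (−0.20), osmotic (−0.39) and mitochondrial (0.19) genes, replicate 2 those of hedgehog-related (−0.03) and mitochondrial (0.13) genes, and replicate 3 those of osmotic (0.030), mitochondrial (0.16) and pathogen response genes (−0.16).

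In all, 18 of 43 tested lists were called with the preset correlation, 9 higher and 9 lower, and 0 with an estimated correlation or by fry. As the latter tests rest on 2 residual degrees of freedom, their 0 calls do not show that the lists were unchanged. The osmotic response list, at an estimated correlation of −0.002, went from an unadjusted p of 0.0168 to 0.131 by camera. Correlation between genes is thus not the only source of the lost calls. Over all lists, 28 genes in 2 lists had an adjusted p under 0.05 adjusted over the list alone. The number called was 10 without replicate 1 of either genotype. The calls of the proteasome and of both sperm lists held under each of 17 other settings of the fit, and those of the other 15 lists were lost or turned in 2 to 12 of the 17. Median, mean and test differed in sign in 4 uncalled lists, the UDP-glucuronosyltransferases, DAF-16 targets, intestine and epidermis genes. The 25 lists not called had medians from −0.51 (cytosolic heat shock genes) to 0.64 (adult cuticle collagens), and they included muscle, neuronal, intestine, pharynx, epidermis and excretory canal genes, heterochronic, vulva and somatic gonad genes, C-type lectins, F-box genes, intracellular pathogen response, ER unfolded protein response, glutathione S-transferase, metal response and lipid metabolism genes, ribosomal proteins, respiratory chain genes, histones, autophagy genes and the targets of DAF-16 and HIF-1. The cytosolic heat shock list passed 0.05 in each fit without 1 library, lower without replicates 1 or 3 (−0.67 and −1.38) and higher without replicate 2 of either genotype (0.23), and the moulting list was at −1.45 without replicate 3. Embryonic zygotic genes and genes of male ciliated neurons had 0 tested members, with mean levels of at most 0.449 and 0.440 RPKM, and mitochondrially encoded genes were not analysed here.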

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

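The scalings, the stricter filter, voom on recovered reads, the robust prior and the moulting score were chosen only after the results were seen. The planned DESeq2 Wald test, edgeR with RLE, upper-quartile or TMM factors, filterByExpr, the filter on CPM and glmTreat were not run, as the deposited values are RPKM. In their place stood limma's treat, scalings of the RPKM and a mean RPKM of at least 5. Of the methods for counts, only voom was run on the recovered reads. The authors' batch term was matched best by the replicate number, but the deviations of same-numbered libraries from their group means correlated at −0.23, −0.28 and −0.59 and so gave no sign that the numbers pair the samples. Without the replicate block 2 genes, mstr-1 and BE0003N10.6 (adjusted p = 0.0450 by limma, 0.0450 to 1.00 over 18 alternatives), passed, 1249 genes had an unadjusted p under 0.05 against 575 with it and about 802 by chance, and 13 lists were called, the vitellogenin, hedgehog-related, osmotic, mitochondrial and PMK-1 pathogen response lists no longer passing. The gene count was 0 to 1 over the fits that left out 1 library, and apart from the fit without the block it was 1 under every other alternative run. mstr-1 kept its direction in all 18 alternatives and passed in 15, with log2 fold changes of −10.07 to −9.98 in the fits that left out 1 library and adjusted p from 3.79e-06 to 0.545 over all 18 by limma. In the fits that left out 1 library, 1 residual degree of freedom remains, and the lost calls of mstr-1 came with estimates inside that range. Lists called numbered 0 with an estimated correlation, 0 by fry, 11 with the moulting score in place of the block and 10 to 23 without 1 library. The scaling moved the median of all genes from 0.02 to 0.01 (median-of-ratios) and −0.05 (upper-quartile).

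Medians that changed sign when 1 library was left out ran from −0.0400 to 2.81 for vitellogenins, −0.45 to 0.23 for cuticle collagens, −0.55 to 0.011 for lysozymes, −0.16 to 0.45 for PMK-1 pathogen response genes, −0.53 to 0.030 for osmotic response genes, −0.33 to 0.043 for neuropeptides, −1.45 to 0.32 for moulting genes, −1.38 to 0.23 for heat shock genes and −0.30 to 3.84 for adult cuticle collagens, the last also at −0.00679 with the moulting score. For the 82 named genes other than mstr-1, 1452 of 1468 values kept direction and side of the threshold. None of these genes passed in the main fit, where their smallest adjusted p was 0.358 by limma. Keeping their side of the threshold is therefore no sign of stability. Log2 fold changes changed sign without 1 library for vit-5 (−0.88 to 4.36), gpdh-1 (−1.25 to 0.030), hmit-1.1 (−1.97 to 0.40), gtnt-16 (−1.08 to 0.35, and 0.15 with the moulting score) and W01A8.6 (−0.23 to 0.0786). The fits without 1 library hold fewer samples, those with the moulting score do not, and the cause was not tested. Depth does not limit mstr-1, with 38603 reads in N2, but F07E5.9 rests on 18 reads in N2.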

Other observations

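The tests with the moulting score, the test of reads shared among major sperm protein genes and the test for N2 animals were chosen only after the result was seen.

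The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. For the gene count, 1 split gave a result as large, the real one with 1 gene, and the highest other had 0. For the 18 called lists, 7 splits gave as many, and the highest other had 22. In 6 of the other splits both libraries of 2 replicate numbers fall on one side each, so that with the block the estimate is the genotype difference of 1 pair, and these are no measure of chance. With the block the proteasome list passed 0.05 in 8 of the 9 other splits, and in the 3 that part every same-numbered pair its median was 0.26 (adjusted p = 0.0118), 0.13 (adjusted p = 1.10e-04) and −0.11 (adjusted p = 0.321), against 0.51 between genotypes. Without the block the genotypes gave 13 lists and 2 genes, each of the other splits gave 14 to 22 lists, and N2 replicates 1 and 2 with mstr-1(on33) replicate 3 against the rest gave 1053 genes, which points to a structure of the samples that does not follow genotype.

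Proteasome genes were higher by a median of 0.51 in mstr-1(on33). The scaling of the libraries is argued against by the median of all genes, 0.02. List medians of 0.498 with median-of-ratios and 0.431 with upper-quartile scaling argue against it as well. With the moulting score as covariate the list median was 0.492 (interquartile range 0.43 to 0.55). That score differed little between genotypes, at 0.12 ± 0.64 in N2 and −0.12 ± 0.97 in the mutant (SD, n = 3). Adjusting for it could therefore move the median little, and developmental stage stays open. A candidate explanation is a programme shared with partner genes of the proteasome. A list of these, with ubiquitin and CDC-48 genes among them, was written before the test. The median of 15 tested partner genes was 0.325 (interquartile range 0.19 to 0.43), and 14 of 15 were higher. In 8 the genotypes did not overlap, where chance gives 10% for a single gene and genes of a list are not independent. The list means gave an exact permutation p of 0.1 (two-sided, the smallest possible). Within the partner list the ubiquitin genes ubq-1 and ubq-2 were at log2 fold changes of 0.14 ± 0.13 and −0.04 ± 0.12. The CDC-48 genes cdc-48.1 and cdc-48.2 were at 0.315 ± 0.155 and 0.325 ± 0.159. An effect of the mstr-1 genotype and other differences between the strains remain untested.

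Both sperm lists were lower, with a median of −0.999 over their 52 genes. With the moulting score as covariate the median was −1.12 (interquartile range −1.29 to −0.90). As that score differed little between genotypes, this does not decide whether developmental stage plays a part. Reads shared between near-identical major sperm protein genes are argued against as the source of the whole pattern by the other spermatogenesis genes. Their median was −0.81 (interquartile range −0.90 to −0.60, and −0.42 without replicate 3 of either genotype). How far shared reads affect the values of the major sperm protein genes themselves was not tested. Sperm genes may still depend on age within the stage in a way that a linear score does not follow, and a genotype effect was not tested apart from that.

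gtnt-17, gtnt-18 and BE0003N10.6, chosen after their values were seen, were lower in each mutant library, at 0.342%, 1.50% and 7.83% (gtnt-17), 2.9025%, 4.13% and 10.7% (gtnt-18) and 2.04%, 3.71% and 6.59% (BE0003N10.6) of the mean N2 level in replicates 1 to 3, with the highest share of each in replicate 3. N2 animals in the mutant samples as the source of the remaining reads are argued against by mstr-1, whose upper 95% limit was 0.0180% of N2, below the smallest share of these genes in any mutant library (0.342%, gtnt-17 in replicate 1). Reads moving to related gtnt genes stay open, since the 51 other gtnt genes gained −41.3% of the loss, at 227 ± 26.5 RPM (reads scaled to the library total) in N2 and 210 ± 42.9 in the mutant, with a standard error of 67.4% that is too wide to decide. Another candidate explanation left open is a sequence difference between the strains at these loci, where the 6 nearest tested genes had median log2 fold changes of 0.13 (gtnt-17) and 0.11 (BE0003N10.6).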
